A study of Homo sapiens with 2 samples.

How the data were processed

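The series holds 2 two-colour Agilent 44K human arrays of HCT116 cells with a disrupted DICER exon 5 against parental HCT116 cells, with the dyes exchanged between the arrays. Both arrays form 1 group of ratios, and the dye of each line was taken from the labels. Replicate numbers follow the order of the records and pair nothing. Per the labels, total RNA was amplified and labelled by in vitro transcription with added spike-in RNAs.

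The deposited scanner files hold spot intensity values, the mean foreground and median background of each channel in linear intensity units, extracted with Agilent Feature Extraction 8.5 per the submitters' processing notes. The same deposited files give a log10 ratio of red over green per spot, after spatial detrending and a linear and LOWESS dye normalization per the file headers. Columns of flags mark control, outlier, saturated and background-level spots. Genome build and annotation version of the probe design are not given in the sources used here. The authors' deposited series table holds values on the log10 scale. Its column for array 1 equalled that array's scanner log10 ratio for 100% of features within 1e-05. Its column for array 2 ran in the opposite direction, with r = -0.872 and a slope of -0.89 against the scanner ratio over features above background, and equalled it for 4.86% of features. Both columns have a median of 0. How the array 2 column was rescaled stays unknown, and the series table entered only as an alternative, with its array 2 column taken as knockout over parental from that correlation. The authors' deposited scanner statistics give a slope of observed on expected spike-in log ratios of 0.876 and 0.884, so the authors' log10 ratios were somewhat compressed.

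Each array has 43931 features, 2256 of them controls. Median signal over non-control spots was 221.9 in red and 141.9 in green on array 1, against a median background of 59 and 48, and 194.3 and 144 on array 2, against 58 and 47. Saturated spots numbered 138 and 14 on array 1 and 98 and 7 on array 2, in red and green. The number of arrays limits the precision, and limma's moderated standard error had a median over genes of 0.072 on the log2 scale.

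The values computed here started from the intensities in R 4.3.3 with limma 3.58.1. Background was corrected by normexp with an offset of 50 on all spots, and log2 ratios were normalized within each array by loess with control spots at weight 0. Control spots were then left out, as were the 25 and 17 spots marked as outliers. Each log2 ratio was turned to knockout over parental. Spots of a probe were averaged, and 35812 of 41000 probes, well above background in at least 1 channel on both arrays, were kept. A gene was represented by its kept probe with the highest mean intensity, which gave 27078 genes, 15937 with a RefSeq symbol. Of the probes, 22445 were named through the accession in the GRCh38.p14 gene table, 2634 through the symbol and 1412 through an older symbol, and 14509 kept the name in the files. Of 6589 genes with over 1 kept probe, 30 had probes over 1 log2 unit apart, and the text names those it reports.

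The turned ratios were fitted with lmFit and eBayes as an intercept against 0, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The fit has 1 residual degree of freedom per gene, which is the dye effect, plus a prior of 14.5 shared over genes. Standard errors are the moderated ones of this fit, so they rest mostly on the prior. A count of genes at least 2-fold apart on both arrays was made beside it. Where the representing probe was not well above background in 1 line on both arrays, the fold is given as at least the bright line's mean over the dim line's mean, each array taken at the higher of the probe's own signal and the lowest signal among probes well above background, per channel after loess and Aquantile. Gene lists fixed before the data were examined were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and list medians were set beside 10000 random lists matched on mean intensity in 20 bins. The genes named are DICER1, the 12 highest and 12 lowest called genes at least 2-fold apart on both arrays with a symbol, and from each list the 4 called members with the largest mean. Members not called are named only where few, and some genes that the rule selects are not reported here.

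The steps were tested on simulated data made from the real intensities, for the comparison of knockout against parental over 27078 genes. Of 67 genes changed by 0.5 on the log2 scale 86.6% were called, with a median estimate of 0.38. All 67 genes changed by 1 and all 66 changed by 2 were called, with median estimates of 0.74 and 1.71, so the offset shrinks the ratios. Of 26728 unchanged genes 11 were called. The simulated errors followed the same prior that the fit assumes, and few genes were changed. That count is therefore not a rate of false calls in the real data. In the simulated list test 5 of 5 shifted lists and 0 of 28 unchanged lists were called. Errors were drawn separately for each gene, so that test says nothing about lists whose genes are correlated.

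Alternatives were no background subtraction, an offset of 0, median centring without loess, Agilent's own log ratio, no filter or a stricter filter on dim probes, outlier spots kept, the mean over a gene's probes, a trended and robust prior, other thresholds, each array left out, the deposited series table and an estimated correlation. An analysis of microRNA seed sites in 3′ untranslated regions was planned and not run, since it needs transcript sequences, which were not used here. Figures were drawn with matplotlib 3.10.9.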

Results

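Gene expression was measured in HCT116 cells, an established human colorectal cancer line, in which exon 5 of DICER had been disrupted, against parental HCT116 cells. DICER cuts microRNA precursors into mature microRNAs, so the comparison addresses how messenger RNA levels differ when this step is impaired. Total RNA of both lines was hybridised together on 2 two-colour Agilent arrays with the dyes exchanged between them. On array 1 the knockout RNA carried Cy5 and the parental RNA Cy3, and on array 2 the dyes were reversed. All values below are log2 ratios of knockout over parental, so that positive values are higher in the knockout. Between 84.7% and 88.4% of non-control spots were well above background in each channel of each array, and 27078 genes were tested. The number of arrays limits the precision. The labels name 1 knockout line and do not say whether the arrays carry separate cultures or the same extracts. Limma p-values of single genes therefore measure only the spread between these arrays, largely pooled over genes, which may be technical. Camera p-values compare the genes of a list with the other genes. None of these p-values is known to cover variation between cultures.

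DICER1 transcript was measured by 2 probes. The brighter probe read 0.65 on array 1 and 0.28 on array 2, a mean of 0.47 ± 0.08 (SE, n = 2 arrays). That is 1.38-fold higher in the knockout, with a limma adjusted p of 0.000838. Each SE given here is limma's moderated one. It rests mostly on the prior shared over genes and can be smaller than the spread of the gene's own values. The other probe read 0.22 and 0.19. The position of the probes relative to exon 5 was not determined here, so these values do not check the disruption. The DICER1 call was lost under 3 other settings, with Agilent's own log ratio, a normexp offset of 0 or median centring without loess, where the mean stayed between 0.51 and 0.53 and the adjusted p lay between 0.0574 and 1.

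Among the gene lists tested, the largest shift in the knockout cells was a loss of interferon-stimulated transcripts, beside a smaller rise of mitotic genes and of several sets of microRNA targets. Limma's camera test called these lists with a preset correlation and none of them with an estimated one (smallest adjusted p = 0.369 with an estimated correlation). IFI27, an interferon-inducible gene, fell by 4.49 ± 0.09 on the log2 scale (SE, n = 2 arrays), 22.4-fold lower in the knockout. IFIT1, whose protein binds foreign RNA, fell by 4.34 ± 0.07, and BST2, which holds budding virus at the cell surface, fell by 3.60 ± 0.08. In the other direction ZBED2, a zinc finger gene, rose by 2.75 ± 0.07 and CDK6, a cyclin-dependent kinase of the G1 phase, by 2.13 ± 0.07, 4.37-fold. Of 31 genes tested from the G2/M list, 30 rose, with a median of 0.51.

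With limma and a Benjamini-Hochberg adjusted p under 0.05, 4780 genes were called, 2711 higher and 2069 lower in the knockout. Most of these changes were small: 83.7% of called genes lay under 1.5-fold, and the median size was 0.33 on the log2 scale. By the rule of size, which needs no p-value, 178 genes were at least 2-fold apart on both arrays, 69 higher and 109 lower, and all 178 were also called. Across genes, which are not independent replicates, the ratios of the arrays had a Pearson r of 0.780 and a Spearman rho of 0.523 once turned to knockout over parental, and 63.6% of genes had the same sign. Before turning, the red over green ratios had an r of -0.780, as exchanged dyes give. Left as red over green, the ratios of the added spike-in RNAs had an r of 0.998, so they followed the dyes. The counts depended on the processing: 2109 genes were called with a normexp offset of 0, 1053 with Agilent's own log ratio and 127, 49 higher and 78 lower, with median centring in place of loess, where the r of the arrays was -0.239. At least 2-fold apart on both arrays were 316 genes with an offset of 0, 392 with Agilent's own log ratio (201 higher, 191 lower), 392 with the deposited series table (199 higher, 193 lower) and 114 with median centring.

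**Figure D1:**
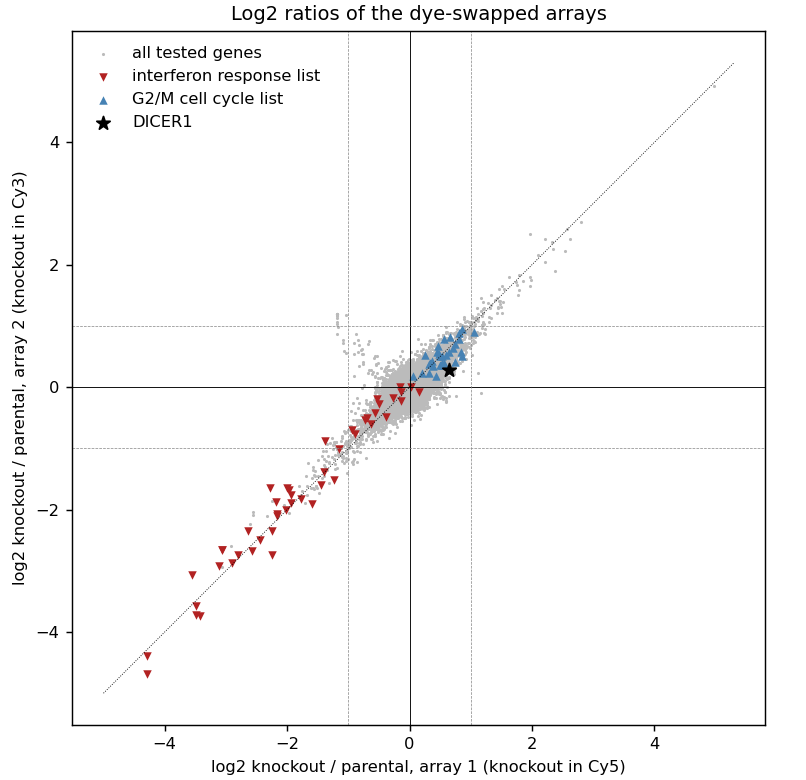
Log2 ratio of knockout over parental on array 1 (x axis) against array 2 (y axis), 1 point per tested gene, with the interferon response and G2/M lists and DICER1 marked and dashed lines at 1 and -1. Interferon list members reach -4.49 in mean near the diagonal, G2/M members lie above 0 on both arrays, and 12 genes lie at least 2-fold apart in opposite directions, among the brightest spots.

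Among the 12 called genes with the highest ratios, several encode structural, secreted or membrane proteins, a grouping that was not tested. KRT23, a keratin, rose by 2.53 ± 0.08 (SE, n = 2 arrays), and MIA, a secreted protein first described in melanoma, by 2.31 ± 0.08. NPR3, the clearance receptor of natriuretic peptides, rose by 2.35 ± 0.07, and ANO1, a calcium-activated chloride channel, by 2.30 ± 0.07. ZNF234 rose by 2.38, LYPD1 by 2.23, DCLK1, a doublecortin-like kinase, by 2.14, and PLAT, the tissue plasminogen activator, by 1.87. A further probe of LYPD1 read 0.23 and 0.10 on the arrays and one of DCLK1 0.23 and -0.01, but neither passed the background filter. The probe that represented PDE4D, a phosphodiesterase of cyclic AMP, was not well above background in the parental cells. The rise at that probe is at least 4.14-fold, which does not bound the rise of the gene. The PDE4D probes disagreed, with means from 0.04 to 2.13 over 4 probes, and those of ANO1 ran from 0.33 to 2.30 over 3 probes. A probe that the files name FLJ14054, outside the naming rule and chosen after its values were seen, had the highest ratio, 4.95.

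The 12 lowest ratios belonged to genes of the interferon response with few exceptions. Besides IFI27, IFIT1 and BST2, they included IFI6 at -3.58, ISG15, a ubiquitin-like modifier, at -3.53, IFI44 at -3.32, IFIT2 at -3.01, OAS3, an oligoadenylate synthetase, at -2.89, SP110 at -2.86, SAMD9 at -2.86 and IFIH1, a cytoplasmic sensor of double-stranded RNA, at -2.77. CSTA, a cysteine protease inhibitor that was not on the interferon list, stood at -3.00. Each of these 12 genes was called with limma, and their moderated standard errors, mostly set by the shared prior, lay between 0.07 and 0.09. The probes of 3 of them differed in size while falling together: IFIT2 probes read -3.01 and -1.84, CSTA probes -3.00 and -1.49, and the 4 SAMD9 probes ran from -2.86 to -0.93.

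**Figure D2:**
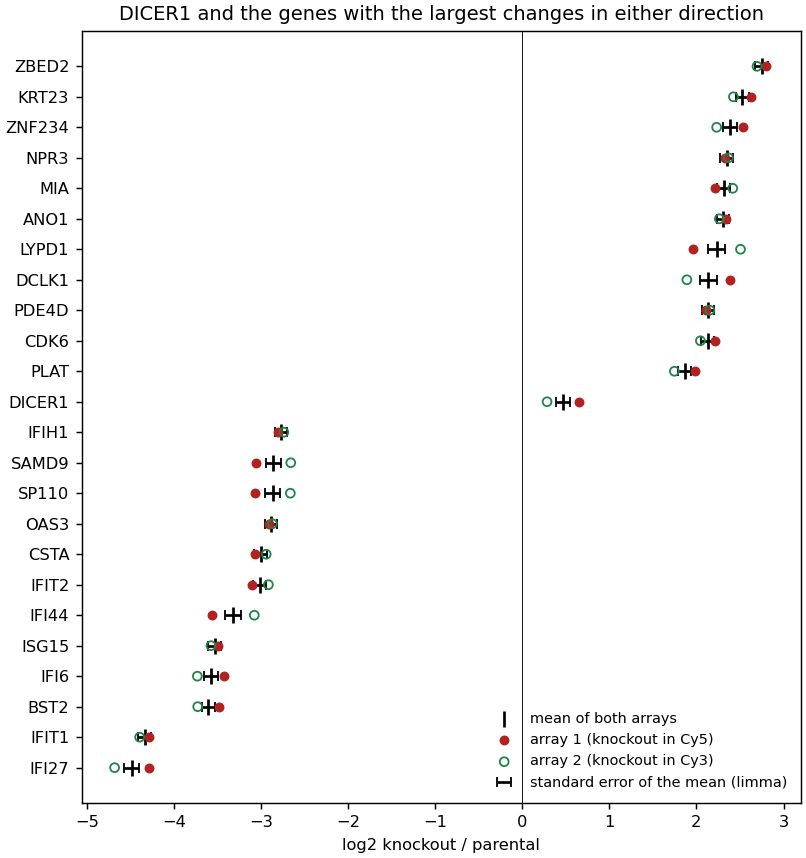
Log2 ratio of knockout over parental for DICER1, 11 of the 12 highest and the 12 lowest called genes that were at least 2-fold apart on both arrays. Filled and open circles are the single arrays, ticks their mean and bars the limma standard error; means run from -4.49 for IFI27 to 2.75 for ZBED2, with DICER1 at 0.47.

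Of 33 gene lists fixed before the data were examined, limma's camera test with a preset correlation called 24, 17 higher and 7 lower in the knockout. With a correlation estimated from the data, which rests on 1 residual degree of freedom, limma called 0 of 33 lists, and 0 had an unadjusted p under 0.05. The adjusted p with an estimated correlation is therefore given with each list below.

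Of 47 genes tested from the interferon response list, 42 fell, 0 rose and 5 were not called; 43 were called adjusted over the list alone. The list median was -1.83, with -1.94 on array 1 and -1.76 on array 2, and 31 members were at least 2-fold lower on both arrays. Its camera adjusted p was 1.35e-72, and the adjusted p was 0.369 with an estimated correlation. Members not called were CXCL10 at -0.18, TRIM22 at -0.11, PSMB8 at -0.08, OAS2 at 0.03 and CXCL11 at 0.01.

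Of 32 genes tested from the NF-kB and inflammatory list, 16 fell and 1 rose, with 21 called adjusted over the list alone. The neutrophil-attracting chemokines CXCL2 and CXCL1 fell by 1.73 ± 0.07 and 1.44 ± 0.08 (SE, n = 2 arrays), LCN2, an iron-binding protein of innate defence, by 1.63 ± 0.07, and BIRC3, an inhibitor of apoptosis, by 1.34 ± 0.07. The member that rose was ICAM1, an adhesion molecule, at 0.62. The median was -0.23 and camera gave an adjusted p of 5.37e-11 (adjusted p = 0.369 with an estimated correlation). Markers of immune cells gave 1 that fell and 0 that rose of 16 tested, with 1 called adjusted over the list alone and a median of -0.03; the member that fell was CD68 at -0.48. That list was not called by camera (adjusted p = 0.153; 0.745 as the adjusted p with an estimated correlation).

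Mitotic genes rose together. In the G2/M list, 30 of 31 genes rose and 0 fell, with 30 called adjusted over the list alone, and the member not called was AURKB at 0.11. CENPF, a centromere protein, rose by 0.98 ± 0.07 (SE, n = 2 arrays), NEK2, a centrosomal kinase, by 0.90 ± 0.07, CCNB2, a mitotic cyclin, by 0.85 ± 0.07, and KIF23, a kinesin of cytokinesis, by 0.80 ± 0.07. In the G1/S list 13 of 28 genes rose and 1 fell, with 15 called adjusted over the list alone and a median of 0.19. CDC25A stood at 0.48, RFC4 at 0.46 and RRM2 at 0.42, and the member that fell was MCM7, part of the replicative helicase, at -0.41. The camera adjusted p was 2.46e-27 for G2/M and 2.9e-06 for G1/S, and the adjusted p was 0.369 for each with an estimated correlation. In the p53 target list 11 of 29 genes fell and 3 rose, with 17 called adjusted over the list alone and a median of -0.12. SFN, a 14-3-3 protein, fell by 0.72, FAS, a death receptor, by 0.61, and GDF15 by 0.52, with -0.85 on array 1 and -0.18 on array 2, while TNFRSF10B, another death receptor, rose by 0.43. The p53 list had a camera adjusted p of 0.0036 (adjusted p = 0.369 with an estimated correlation). Its call was lost with median centring, at a camera adjusted p of 0.0935, though its median there was -0.13.

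Of 8 lists of microRNA targets, 7 were called higher in the knockout with a preset correlation and 0 with an estimated one (adjusted p = 0.369 to 0.444 for these 7 with an estimated correlation). Over the 158 distinct target genes tested, 57 rose, 12 fell and 89 were not called, with a median of 0.12. In the miR-200 family list 10 of 20 genes rose and 1 fell, with 12 called adjusted over the list alone and a median of 0.22. JAG1, a Notch ligand, rose by 1.43 ± 0.07 (SE, n = 2 arrays), CFL2, an actin-severing protein, by 1.32 ± 0.08, KLF9 by 1.25 ± 0.07, and RECK, an inhibitor of metalloproteinases, by 0.99 ± 0.07. In the miR-15/16 list 10 of 23 rose and 0 fell (12 adjusted over the list alone, median 0.20), led by CDK6, WNT3A at 1.13, RECK and WEE1 at 0.53. In the miR-29 list 8 of 24 rose and 1 fell (11 adjusted over the list alone, median 0.16), with the DNA methyltransferase DNMT3B at 0.61 and PIK3R1 at 0.58. In the miR-21 list 11 of 23 rose and 2 fell (14 adjusted over the list alone, median 0.15), with RHOB at 0.71 and CCL20 at -0.67. With Agilent's own log ratio CCL20 stood at -2.29 and RHOB at 1.15.

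In the list of miR-192 and miR-215 targets 8 of 17 rose and 1 fell (11 adjusted over the list alone, median 0.20), with RACGAP1 at 0.61, MAD2L1 at 0.51, RB1 at 0.41 and MCM10 at -0.37. In the miR-17 family list 9 of 25 rose and 3 fell (15 adjusted over the list alone, median 0.09), with BAMBI at 0.73, TGFBR2 at 0.50, FBXO31 at -0.46 and ZNFX1 at -0.42; its medians on the single arrays were 0.12 and 0.23. The other FBXO31 probe read 0.26 and 0.18, and with the mean over probes FBXO31 was not called, at -0.12 with a limma adjusted p of 0.3. In the miR-34a list 7 of 21 rose and 1 fell (9 adjusted over the list alone, median 0.06), with CDK6, JAG1, AREG at 0.54 and CD44 at -0.95. Its medians on the single arrays were 0.10 and 0.02, and without members of other lists, a setting chosen after seeing the data, the miR-34a list was not called (median -0.002, adjusted p = 0.861). Among the called target lists the camera adjusted p was 1.41e-05 for miR-200 and for miR-15/16, 9.14e-05 for miR-29, 0.0021 for miR-21, 0.0022 for miR-192 and miR-215, 0.00567 for miR-17 and 0.00758 for miR-34a. With an estimated correlation the adjusted p was 0.444 for miR-17 and 0.369 for each of the others. The let-7 list was not called (camera adjusted p = 0.215; adjusted p = 0.701 with an estimated correlation): 6 of 22 genes rose and 3 fell, with 11 called adjusted over the list alone. With median centring the let-7 list was called higher, at an adjusted p of 0.0127 with a median of -0.04. Its median was otherwise -0.002 while its mean was 0.13, with CDK6 at 2.13, NRAS at 0.52, CDC25A at 0.48 and E2F5 at -0.43. The median of each called target list stayed above 0 under every other background, normalization, filter and probe setting.

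The microRNA machinery list, called higher, had 8 of 21 genes that rose and 2 that fell, with 12 called adjusted over the list alone and a median of 0.16. AGO2, the slicing Argonaute protein, rose by 0.67 ± 0.07 (SE, n = 2 arrays) and PRKRA, a DICER partner, by 0.59 ± 0.07. The members that fell were ADAR, an RNA-editing enzyme that is itself interferon-inducible, at -0.78, and the helicase MOV10 at -0.67. The camera adjusted p was 0.00329 (adjusted p = 0.369 with an estimated correlation).

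Of 29 epithelial markers 10 fell, 1 rose and 18 were not called, with 11 called adjusted over the list alone and a median of -0.10. ELF3, an epithelial transcription factor, fell by 1.11 ± 0.09 (SE, n = 2 arrays), AP1M2 by 0.74 ± 0.08 and RAB25 by 0.62 ± 0.08, while MAL2 rose by 0.48 ± 0.07. Of 24 mesenchymal markers 4 rose and 1 fell, with 5 called adjusted over the list alone and a median of 0.04. VIM, an intermediate filament, rose by 1.71, SPARC by 0.55 and FN1, fibronectin, by 0.42, while ACTA2 fell by 0.47. Camera gave an adjusted p of 0.00235 for the epithelial and 0.0435 for the mesenchymal list, against an adjusted p of 0.444 and 0.439 with an estimated correlation. The mesenchymal call was lost with median centring (median -0.001, adjusted p = 0.069), with no filter on dim probes (adjusted p = 0.0594), with both channels above background (adjusted p = 0.0627) and without members of several lists (adjusted p = 0.602), and its median reached 0.12 with Agilent's own log ratio.

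Lists of targets of several signalling pathways were called higher with the preset correlation and not with an estimated one. In the Wnt target list 14 of 28 genes rose and 5 fell (19 adjusted over the list alone, median 0.17), with AXIN2, a feedback inhibitor of the pathway, at 1.41, RNF43 at 0.89 and 1.11 on the single arrays, JAG1 at 1.43 and CD44 at -0.95. In the TGF-beta and YAP list 13 of 25 rose and 3 fell (18 adjusted over the list alone, median 0.25), with AMOTL2 at 1.69, ID2 at 1.09 and the cell cycle inhibitor CDKN2B at -1.49; the other AMOTL2 probe read -0.05, and the mean over probes was 0.82. In the immediate early and MAPK feedback list 13 of 31 rose and 1 fell (18 adjusted over the list alone, median 0.20), with the phosphatase DUSP6 at 1.32, KLF2 at 0.96, EREG at 0.91 and ETV4 at 0.79. The other KLF2 probe read -0.05 and -0.03, and the mean over probes was 0.46. The camera adjusted p was 0.000592 for Wnt, 0.0023 for TGF-beta and YAP and 1.41e-05 for the immediate early list. The adjusted p was 0.441, 0.369 and 0.369 with an estimated correlation.

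Among HOX genes 10 of 35 rose and 0 fell (11 adjusted over the list alone, median 0.04). HOXB6 stood at 0.91, HOXB5 at 0.80, HOXB2 at 0.73 and HOXB8 at 0.72, and 6 of 10 HOXB, 3 of 11 HOXA, 1 of 7 HOXC and 0 of 7 HOXD genes rose, a division by cluster that was made after the values were seen and was not tested. In the DNA methylation and Polycomb machinery list 10 of 28 rose and 2 fell (13 adjusted over the list alone, median 0.11), with MBD4 at 0.75, DNMT3B at 0.61, MBD1 at 0.46 and BMI1 at -0.52. The other MBD1 probes read near 0, and with the mean over probes MBD1 was not called, at 0.17 with a limma adjusted p of 0.0992. In the unfolded protein and ATF4 response list 9 of 30 rose and 0 fell (15 adjusted over the list alone, median 0.16), with MTHFD2 at 0.56, TRIB3 at 0.56, HERPUD1 at 0.42 and XBP1 at 0.41. For these lists the camera adjusted p was 0.0036 for HOX, 0.00659 for the methylation and 0.00326 for the unfolded protein list, against an adjusted p of 0.369, 0.369 and 0.444 with an estimated correlation. With median centring the HOX list was still called, though its median turned to -0.03.

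Metabolic and ribosomal lists were called lower with the preset correlation and not with an estimated one. In the hypoxia and glycolysis list 9 of 29 genes fell and 1 rose (13 adjusted over the list alone, median -0.13), with P4HA1, a collagen prolyl hydroxylase, at -1.06, HK2, a hexokinase, at -0.91 and PFKP at -0.74, while SLC2A1, a glucose transporter, stood at 1.37. In the mitochondrial respiratory chain list 10 of 50 fell and 1 rose (11 adjusted over the list alone, median -0.11), with NDUFS3 at -0.58, ATP5F1C at -0.56, COX6B1 at -0.53 and COX5B at -0.34. Of 73 cytosolic ribosomal protein genes 9 fell and 3 rose (14 adjusted over the list alone, median -0.13; medians of -0.21 on array 1 and -0.03 on array 2), with RPL36 at -0.50, RPS9 at -0.37, RPL39 at -0.30 and RPL22 at 0.53. Of these ribosomal genes 39 were saturated in a channel on an array, and without saturated genes the median was -0.11 with a camera adjusted p of 0.0112. With camera the adjusted p was 0.000592 for hypoxia, 0.000808 for the respiratory chain and 0.000592 for the ribosomal list. With an estimated correlation the adjusted p was 0.369, 0.369 and 0.444. The respiratory chain call was lost with median centring, at an adjusted p of 0.096.

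The remaining lists were not called. Of 40 genes reported as silenced by promoter methylation in colorectal cancer, 7 rose and 3 fell (11 adjusted over the list alone, median -0.01, mean 0.07), with VIM, RECK and RUNX3 at 0.72 among those that rose and BNIP3 at -0.69. Of 25 cholesterol synthesis genes 8 rose and 2 fell (14 adjusted over the list alone, median 0.02), with SC5D at 0.49, ACAT2 at 0.40 and SQLE at -0.50. Of 28 colon differentiation markers 1 rose, CDX2 at 0.39, and 0 fell (1 adjusted over the list alone, median -0.03). Of 16 stem-like markers 2 rose, CD24 at 0.53 and NANOG at 0.22, and 2 fell, CD44 and BMI1 (4 adjusted over the list alone, median -0.02). Of 29 cancer-testis antigens 3 fell, MAGEA4, MAGEA6 and MAGEA12, at -0.23, -0.22 and -0.22, and 0 rose; 0 were called adjusted over the list alone, and these close paralogs may share probe signal. Of 15 fibroblast and endothelial markers 1 fell, ACTA2 at -0.47, and 0 rose (1 adjusted over the list alone, median -0.03). Of 15 neuronal and neuroendocrine markers 2 rose, SYT1 at 1.02 and MAP2 at 0.33, and 1 fell, the granin SCG2 at -2.21 (3 adjusted over the list alone, median -0.03). For these lists the adjusted p of camera was 0.496 for the silenced genes, 0.0786 for cholesterol synthesis, 0.502 for colon differentiation, 0.245 for stem-like markers, 0.215 for cancer-testis antigens, 0.444 for fibroblast and endothelial markers and 0.762 for neuronal markers. In the same order, the adjusted p was 0.846, 0.494, 0.826, 0.521, 0.697, 0.656 and 0.826 with an estimated correlation. The cholesterol synthesis list was called higher with median centring, with a median of 0.07 and an adjusted p of 0.0189.

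Several sizes or calls given above depended on the processing or on 1 array. The call of GDF15 was lost with a normexp offset of 0, median centring or Agilent's own log ratio, at a limma adjusted p of 0.0911, 1 and 0.225. Its size did not shrink there, at -0.53, -0.60 and -0.53. Among the 125 named genes median centring ended the call of 87 and Agilent's own log ratio that of 48. With Agilent's own log ratio several ratios were larger: ZNF234 stood at 3.92, NPR3 at 3.90, LYPD1 at 3.82, VIM at 3.24, RECK at 1.56, HOXB2 at 1.51, CD68 at -1.12, ACTA2 at -0.89, FN1 at 0.85, MAP2 at 0.51 and NANOG at 0.42. With the mean over probes SAMD9 stood at -1.64, PDE4D at 0.80, HK2 at -0.53, CCNB2 at 0.47, HOXB2 at 0.45, RPL22 at 0.29 and RB1 at 0.20. The single arrays read -0.32 and -0.71 for BMI1, 0.22 and 0.62 for HERPUD1, -0.56 and -0.27 for MCM7, -0.52 and -0.22 for RPS9 and -0.32 and -0.14 for MAGEA4. List medians on the single arrays were 0.27 and 0.14 for miR-200, 0.22 and 0.07 for miR-21, 0.21 and 0.10 for miR-29, -0.21 and -0.12 for p53 and 0.05 and 0.07 for the mesenchymal list. Over the settings for background, normalization, filter and probes, list medians ran from 0.08 to 0.31 for miR-200, 0.07 to 0.19 for miR-17, 0.10 to 0.30 for Wnt targets, 0.20 to 0.43 for TGF-beta and YAP targets, 0.05 to 0.13 for the methylation list and -0.42 to -0.21 for the NF-kB list.

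**Figure D3:**
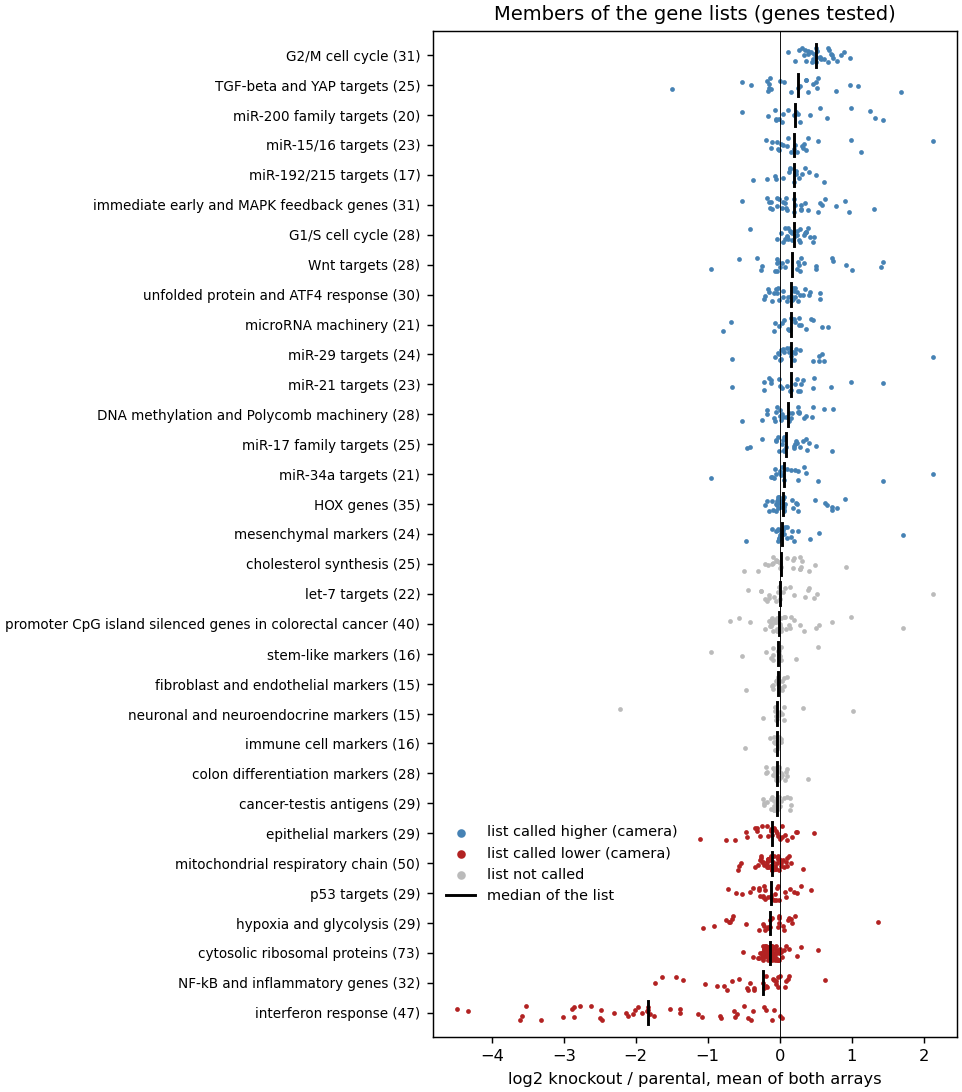
Mean log2 ratio of knockout over parental (x axis) of every tested member of the 33 gene lists (y axis, number of genes tested in brackets), with the list median as a black tick. Blue and red points are lists called higher and lower by camera with a preset correlation; the interferon list median of -1.83 and the G2/M median of 0.51 lie at the ends.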

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

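A signal was present in probes that the gene comparison leaves out. Of the 11 spike-in control probes, 10 were well above background in both channels on both arrays. Their ratios followed the dye and not the cell line, with r = 0.998 between the arrays before any turning and the same sign for 10 of the 11. Per the labels these RNAs were added to the samples, and the scanner statistics set their log ratios against expected ones. The signal therefore comes from the added RNAs and not from the cells.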

How the results depend on the processing

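The settings without members of several lists and without saturated genes were chosen after seeing the data. Called genes numbered 4780 on the main setting, 2109 with a normexp offset of 0, 1053 with Agilent's own log ratio, 127 with median centring in place of loess and 3029 at an adjusted p under 0.01. Median centring also moved the share of higher calls from 56.7% to 38.6%. Genes at least 2-fold apart on both arrays numbered 178 on the main setting, 316 with an offset of 0, 114 with median centring, 392 with Agilent's own log ratio and 392 with the deposited series table. At 1.5-fold there were 624 and at 3-fold 65. The higher share of these genes was 38.8%, and 51.3% with Agilent's own log ratio, 50.8% with the series table and 53% at 1.5-fold. With 1 array left out, the count at least 2-fold on the other ranged from 211 to 253, with no test. The r of the arrays was 0.780, and 0.679 with an offset of 0, -0.239 with median centring, 0.606 with Agilent's own log ratio, 0.763 with no filter on dim probes, 0.785 with both channels above background, 0.764 with outlier spots kept and 0.795 with the mean over probes. DICER1 stayed higher in all settings; it was no longer called with an offset of 0 (0.51), median centring (0.53) or Agilent's own log ratio (0.52), with adjusted p from 0.000256 to 1 over its alternatives. With an estimated correlation 0 lists were called, against 24, with 1 residual degree of freedom left to estimate it; otherwise 20 to 24 lists were called, 20 of them without members of several lists. For these changes the cause was not tested. With median centring, though, the r of -0.239 means that ratios across genes followed the dye more than the cell line. None of the 125 named genes turned sign under the settings tried, and 38 were called under every one; 87 lost their call with median centring and 48 with Agilent's own log ratio. The seed-site analysis and its alternatives were not run. Dim genes near background have compressed ratios under the offset, which limits what the arrays show for them.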

Other observations

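The lists in this part were chosen after seeing the data, as were the tests of dye effect, immune cells and other line differences and those of the largest chromosome run alone. Camera p-values of the lists in this part were adjusted over those lists alone. They do not account for the choice of the lists. Of 21 genes of MHC class I antigen presentation, 16 fell and 0 rose, with a median of -0.82 and a camera adjusted p of 5.67e-23 (adjusted p = 0.231 with an estimated correlation). The list shares PSMB8, PSMB9 and TAP1 with the interferon response list, and without these 3 genes 14 of 18 fell, with a median of -0.71 and an adjusted p of 1.1e-19 (adjusted p = 0.248 with an estimated correlation). PSMB9, an immunoproteasome subunit, stood at -2.11 ± 0.07 (SE, n = 2 arrays), TAP1, a peptide transporter, at -1.38 ± 0.08, and B2M, the light chain of class I molecules, at -1.76, with its other probe at -0.31. HLA-F and HLA-B stood at -1.46 and -1.27, values that are uncertain for each gene because these paralogs share sequence. Of 22 interferon ligands, receptors, kinases and other signalling genes, 3 fell, STING1 at -0.60, TICAM1 at -0.40 and IRF2 at -0.27. These 3 are adaptors or a transcription factor and not ligands, receptors or kinases. The 2 that rose were IFNE, a ligand, at 0.99 and TYK2, a kinase, at 0.23. That list was not called (adjusted p = 0.206; adjusted p = 0.553 with an estimated correlation), and IFNB1 stood at -0.06.

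Of 18 circadian clock genes 8 rose and 1 fell, with a median of 0.16 and a camera adjusted p of 5.79e-06 (adjusted p = 0.248 with an estimated correlation). PER2, a repressor of the clock, stood at 1.21, with its other probe at 0.18, BHLHE41 at 0.97, CRY2 at 0.86 and BHLHE40, which fell, at -0.47. Among 32 Wnt, FGF and BMP ligands and related genes 6 rose and 4 fell, GDF15 among the latter. The list was not called by camera (adjusted p = 0.459, and adjusted p = 0.553 with an estimated correlation). FGF9 stood at 1.81, BMP4 at 1.42 and FGF18 at 1.13.

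The first pattern weighed is the fall of interferon response genes. A gene-specific dye effect would leave a shift in red over green averaged over both orientations, where the list median was -0.0318, against -1.83 once turned. Immune cells in the parental culture would lower their own markers, whose median was -0.0342, and only CD68 of the 16 was called. The offset compresses ratios of dim genes, and CD68 stood at -1.12 with Agilent's own log ratio, against -0.48. Under the other settings for background, normalization, filter and probes the marker median stayed between -0.08 and -0.03. A small share of such cells is not excluded. A difference between the lines other than DICER, such as clonal selection, stays open, because the labels name 1 knockout line, which cannot be told apart from an effect of its clone. An interferon state of the parental culture that depends on DICER is a hypothesis that these arrays do not test.

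The second pattern is the higher median of microRNA target lists. Shared genes are not the whole cause: without the 12 members of more than 1 target list, 5 of the 8 lists were still called higher, though without members shared with any list the miR-17, miR-21 and miR-34a lists lost their call. Without members of the cell cycle lists 7 of 8 lists were still called, so those shared members alone do not explain the rise. Other cell cycle genes, such as CDK6, stayed in the target lists, so a wider cell cycle shift stays open. For the expression level of the target genes, 6 of the 8 medians lay at or above the 95th percentile of random lists matched on intensity. Called higher were 7 of the 8 target lists, against 17 of all 33 lists, which include these 7. Higher calls were thus more frequent among target lists but not confined to them, and 7 of the 33 lists were called lower. Medians were 0.25 for TGF-beta and YAP targets, 0.20 for immediate early genes and 0.19 for G1/S, against 0.06 to 0.22 for the called target lists. A candidate explanation is weaker repression by microRNAs in the knockout, as a hypothesis found and tested on the same arrays. Its direct test, seed sites in the untranslated regions, was not run. No list was called with an estimated correlation. That setting has 1 residual degree of freedom and did not call even the interferon list, so it cannot tell whether the calls hold.

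The third pattern is runs of neighbouring genes that shifted together: with genes in chromosomal order, the running median over 61 genes reached -0.295 at the start of chromosome 10, and in a permutation test 0 of 1000 random orders reached that size (p = 0.001, the smallest they can give). From TUBB8 to CXCL12 the median of 145 genes was -0.21, with -0.20 and -0.21 on the arrays. Of these genes 71 were called lower, such as GDI2 at -1.35 and GTPBP4 at -0.96, and 7 higher. Further along chromosome 10 weaker runs went higher, with medians of 0.11 from DKK1 to SGPL1 and 0.098 from TRIM8 to EDRF1. Another weaker run, on chromosome 19, rested on 1 array, with medians of -0.10 and -0.01. In 5 of the 8 runs every quadrant of the array kept at least 0.579 of the run's median, which argues against probe position there. The lowest share was 0.734 in the run from TUBB8 to CXCL12. In the other 3 runs the lowest quadrant kept 0.083 (TRIM8 to EDRF1), 0.0268 and -0.0946, so position stays open for them. A copy number difference may underlie the runs and was not excluded. Lower were 77.2% of genes in the run from TUBB8 to CXCL12, against 52.2% of all placed genes. In the run with the lowest share, on chromosome 8, 63.5% were higher, against 47.8% of all placed genes. These shares count dim genes, whose ratios are compressed. In the run from TUBB8 to CXCL12 the dimmer genes had a median of -0.07 and the brighter ones -0.32.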
